A study of Mus musculus with 4 samples.

How the data were processed

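Embryos of the ICR mouse strain, an outbred laboratory stock, were produced by in vitro fertilization and electroporated at the 1-cell stage, at 3 hpi, with control siRNA or with siRNA against Pwp1. They were cultured in KSOM medium with bovine serum albumin to the morula stage, at 72 hpi, and 10 morulae went into each library. Libraries were made from polyadenylated RNA with a SMART-Seq kit, per the labels. The 4 libraries fall into 2 groups of 2, taken from the sample titles. The labels say that the experiments were duplicated and not whether the replicates were separate cultures, so p-values measure only the spread between these libraries.

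The deposited files hold RSEM expected counts per gene for each library, not normalized, per the file headers. They also hold TPM, scaled by the authors within each library, per the file headers. The FPKM in the deposited files were likewise made by the authors, with effective gene length in the scaling. The labels name STAR 2.7.10, RSEM 1.3.3 and the mm10 build. Trimming, the annotation release and the strand setting are not given in the sources used here. Each file lists 24411 genes by symbol with their RefSeq transcripts and no gene of the mitochondrial genome. RSEM divides reads that match several copies of a gene among them, so levels within multi-copy families are uncertain copy by copy. Genes that overlap on opposite strands may share reads where the library does not keep the strand.

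Expected counts were rounded to whole numbers and tested with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, with group as the single term. The filter was filterByExpr with its minimum count of 10, and the scaling was TMM. This left 13585 genes. P-values are two-sided and were adjusted by the Benjamini-Hochberg method, with a threshold of 0.05. Levels are CPM scaled by TMM, given as mean ± SD (n = 2) in siControl and then in siPwp1, or for each library. Log2 fold changes are siPwp1 minus siControl, and each standard error (SE) is the absolute log2 fold change over the square root of the F statistic. A count of 3 corresponds to 0.0615 to 0.104 CPM, depending on the library, and this floor covers counting error only. A gene was called separated when both siPwp1 libraries lay above, or both below, both siControl libraries. Chance gives this for 16.7% of genes in each direction if the 4 libraries vary alike and independently. A two-sided exact permutation test of 2 against 2 cannot go below p = 0.333. FPKM were not used, and TPM only in a test with limma 3.58.1 on log2(TPM + 1), chosen after seeing the data.

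Before the data were examined, 28 gene lists, the tests, the alternatives and the rule for named genes were fixed. The 26 lists with at least 5 measured members were tested with limma's camera on log2 CPM (prior count 2) at a preset correlation of 0.01, and again with an estimated correlation. The fry test was also run, which asks whether the genes of a list move on balance in one direction, without comparing them with other genes. With an estimated correlation camera, like fry, rests on the few residual degrees of freedom of 4 libraries. A call lost there may thus reflect the number of libraries, correlation between genes or both. The sperm list, with 3 measured members, and the mitochondrial genome list, with 0, were not tested.

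The rule named Pwp1, 13 markers, 10 genes per direction and up to 4 members of each list with the smallest unadjusted p. The 10 per direction were called genes with a mean of 5 CPM or more in the higher group and separated libraries, filled up with uncalled genes of smallest unadjusted p that met the same conditions. Symbols that are only identifiers were counted but not named. After the values were seen, the members named were narrowed to 4 for each called list and at most 2 for each other list, and list members that passed over their list alone were added.

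The tests were tried on data simulated from the mean levels, library sizes and dispersions of these libraries, for the comparison of siPwp1 with siControl, with independent errors for each gene. Of 12989 genes run, 12799 were unchanged. edgeR called 1.61% of the genes changed 2-fold, 40.9% of those changed 4-fold, 61.3% of those changed 8-fold and 7 unchanged genes. DESeq2 called 8.33%, 74.2% and 79.7% of the changed genes in the same order, and 49 unchanged genes. Of 200 unchanged lists of 28 genes, 8 had a camera p under 0.05. Members of a real list do not vary independently, which this simulation leaves out.

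The alternatives were no filter on low counts, a stricter filter of 5 CPM in at least 2 libraries, DESeq2 size factors, the Wald test of DESeq2 1.42.0, the replicate number as a block, each library left out in turn, and a threshold of 0.1. Where a group keeps 1 library, that library is assumed to vary like the other group. Gene positions are from GENCODE release M21 on GRCm38, the assembly that mm10 names.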

Results

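The data are RNA-seq counts from mouse morulae that received control siRNA (siControl, 2 libraries) or siRNA against Pwp1 (siPwp1, 2 libraries) at the 1-cell stage, with 10 embryos per library. Pwp1 encodes a WD-repeat protein known for roles in ribosomal RNA synthesis and in chromatin. The expected counts summed to 28981358 and 44985949 in siControl replicates 1 and 2, and to 48765229 and 30356988 in siPwp1 replicates 1 and 2. Between 15149 and 15976 genes had a count above 0, and the 10 most abundant genes took 6.99% to 8.59% of counts. Across genes, which are not independent replicates, log2 CPM correlated at 0.933 between the siControl libraries, 0.936 between the siPwp1 libraries and 0.905 to 0.947 between libraries of different groups. Libraries of 1 group were no more alike than libraries of different groups.

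The comparison of siPwp1 with siControl asks how transcripts of the morula differ when Pwp1 is targeted. Pwp1 itself was 7.83-fold lower in siPwp1. It stood at 215.4 and 364.9 CPM in the siControl libraries and at 36.9 and 37.2 CPM in the siPwp1 libraries, with group values of 290.2 ± 105.7 and 37.1 ± 0.251 CPM (SD, n = 2). The gene lies on chromosome 10 from 85829494 to 85889096 on the plus strand (GRCm38), is protein-coding with up to 15 exons per transcript, and is listed in the files with NM_133993. Its log2 fold change was -2.97 (SE 0.333), with an adjusted p = 5.24e-05 over this 1 gene and an adjusted p = 0.22 over all 13585 genes with edgeR. DESeq2 gave an adjusted p = 1.47e-12 over the same genes. Over all genes edgeR did call Pwp1 once a library was left out: adjusted p = 0.00847 without siControl replicate 1, 9e-05 without siControl replicate 2, 3.87e-05 without siPwp1 replicate 1 and 6.84e-05 without siPwp1 replicate 2. In those fits edgeR's prior degrees of freedom for the spread were 9.8, 23.7, infinite and infinite, against 4.84 with all libraries. The same F statistic thus gives a smaller p in fits without a library. The spread and the fold change differ between these fits as well, and their shares were not tested.

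Genes of the 2-cell stage, which the mouse embryo transcribes in a burst when it first activates its genome and then silences, were higher in siPwp1. Of the 28 measured members of this list, 18 were separated and higher, 17 of them by at least 2-fold, and 0 were separated and lower, where chance gives 16.7% in each direction. The median log2 fold change was 2.13, with a camera adjusted p = 6.52e-16. That call was lost with an estimated correlation (adjusted p = 0.856 with an estimated correlation), and fry gave an adjusted p = 0.864. Adjusted over the list alone, edgeR called 6 members higher, namely Usp17lc, Zscan4d, Tcstv3, Obox3, Zfp352 and Zscan4f. Over all genes edgeR called 0 members, while 13 had an unadjusted p under 0.05 and DESeq2 called 6. Zfp352 and Zscan4f lie outside the rule for named genes and were chosen after their values were seen.

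Usp17lc, a deubiquitinase gene, stood at 0.441 ± 0.084 CPM in siControl and 6.57 ± 0.648 CPM in siPwp1 (SD, n = 2), or 14.7-fold higher. Zscan4d, of a zinc finger family that marks the 2-cell stage, stood at 0.927 ± 0.603 and 11.4 ± 2.58 CPM, or 12.5-fold higher. Tcstv3 stood at 2.26 ± 0.53 and 20.3 ± 11.8 CPM, and Zfp352 at 5.61 ± 3.27 and 38.3 ± 24.5 CPM. Obox3, a homeobox gene of oocytes and early embryos, was at 1.18 and 0.0683 CPM in the siControl libraries and at 14.45 and 24.1 CPM in the siPwp1 libraries. Zscan4f was at 0.174 and 1.18 CPM in siControl and at 26.6 and 4.38 CPM in siPwp1. Zscan4d lies on chromosome 7 at 11161374 to 11166159, Usp17lc on chromosome 7 at 103415072 to 103419880, and Tcstv3 on chromosome 13 at 120316878 to 120318178. All of these genes but Zfp352 belong to multi-copy families, so the share of each copy is uncertain, and Obox3 also overlaps Obox1 on the other strand. The summed Obox family was not separated, at 424.2 and 1219 CPM in siControl and 855.4 and 1434 CPM in siPwp1. Reads assigned to Obox3 in place of other Obox copies thus stay possible. Replicate 2 was above replicate 1 for this list within each group too, with median log2 differences of 1.58 in siControl and 0.67 in siPwp1. Without siControl replicate 2 the list's median was 3.67. Over all genes edgeR called Obox3 without any 1 of the 4 libraries (adjusted p = 0.011 without siControl replicate 1, the highest), Zfp352 without siControl replicate 2 (adjusted p = 0.00164) or siPwp1 replicate 1 (adjusted p = 7.86e-06), and Zscan4f without siControl replicate 2 (adjusted p = 0.000774) or siPwp1 replicate 2 (adjusted p = 9.45e-10).

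**Figure D1:**
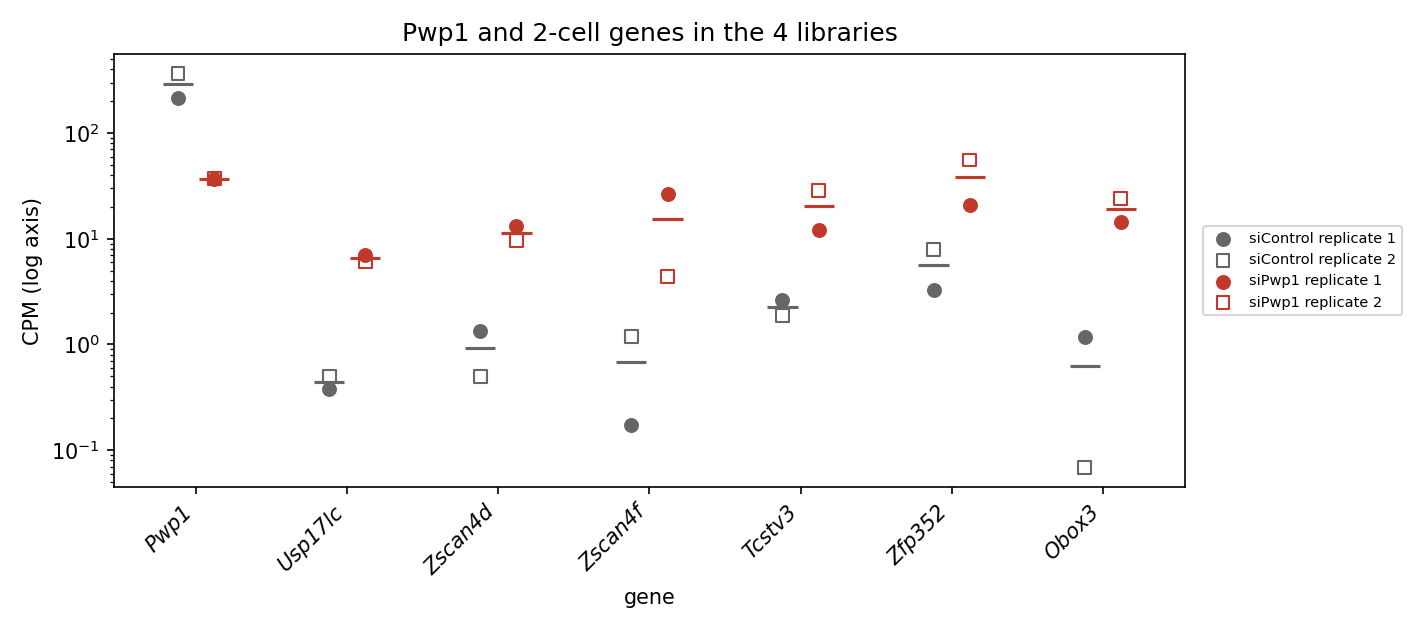
CPM on a log axis for Pwp1 and the 6 members of the 2-cell list called over the list alone, with 1 point per library (siControl grey, siPwp1 red; filled circles replicate 1, open squares replicate 2) and bars at group means. Pwp1 is lower in both siPwp1 libraries (36.9 and 37.2 CPM against 215.4 and 364.9), and each of the 6 others is higher in both.

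Across the transcriptome, edgeR with group as the single term called 0 genes higher and 0 lower in siPwp1. Calls with the replicate number as a block are given further below. At unadjusted p under 0.05 there were 250 higher and 112 lower, 362 in all, where chance gives 679 among 13585 genes. The split of replicate 2 against replicate 1 gave 2263 with edgeR. That difference between replicate numbers counts as spread in the fit by group, so a count under chance does not show that change is absent. DESeq2 called 42 higher and 2 lower, and limma on log2(TPM + 1) called 0 and 0 of 9921 genes. On simulated data of this design DESeq2 called 49 unchanged genes, beside 5, 46 and 47 genes changed 2-fold, 4-fold and 8-fold. The simulation holds no difference between replicate numbers, so 49 is not an estimate of the false calls in these data. The real DESeq2 calls include Pwp1 and 6 members of the 2-cell list. Separated genes numbered 1991 higher (14.7%) and 1909 lower (14.1%), where chance gives 16.7% each. Of these, 857 were at least 2-fold higher and 323 at least 2-fold lower. For replicate 2 against replicate 1 the separated 2-fold genes numbered 931 higher and 1173 lower. Leaving out 1 library moved the edgeR counts to 5 higher and 1 lower without siControl replicate 1, 130 and 12 without siControl replicate 2, 84 and 18 without siPwp1 replicate 1, and 33 and 5 without siPwp1 replicate 2. The prior degrees of freedom differ between these fits as given for Pwp1, so the counts do not compare like with like. The separated 2-fold counts became 1488 and 525, 1800 and 1046, 1530 and 1359, and 1203 and 692 in the same order.

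Among the 10 genes named on the higher side, 0 passed edgeR over all genes with group as the single term. DESeq2 called each, with adjusted p values from 1.03e-10 (Olfr995) to 0.00591 (Ercc4). The genes were picked by edgeR p and separation in these same libraries, so the DESeq2 calls are not independent evidence. Olfr995, an olfactory receptor gene on chromosome 2 at 85437528 to 85443639, was at 0.299 ± 0.0684 and 8.78 ± 1.47 CPM (log2 fold change 4.88, SE 0.58, edgeR adjusted p = 0.22). Slc4a10, a sodium bicarbonate transporter gene, was at 1.04 ± 0.929 and 26.4 ± 11.6 CPM, and Ebf1, a transcription factor gene, at 0.466 ± 0.176 and 6.21 ± 2.58 CPM. The adenylate cyclase gene Adcy2 was at 0.754 ± 0.455 and 11.03 ± 6.62 CPM, and the phosphoinositide phosphatase gene Inpp4b at 0.881 ± 0.46 and 9.49 ± 5.61 CPM. Spesp1, known from sperm, was at 5.28 ± 0.931 and 21.8 ± 1.86 CPM, and Ercc4, a DNA repair nuclease gene, at 7.37 ± 1.22 and 24.3 ± 3.83 CPM. Usp17lc, Zscan4d and Tcstv3 complete the 10. Adcy2, Ebf1 and Inpp4b overlap genes on the other strand, so their levels are uncertain. Some edgeR calls came with a library left out, in fits with higher prior degrees of freedom. Olfr995, Usp17lc, Slc4a10, Zscan4d, Tcstv3, Adcy2 and Inpp4b were called without siControl replicate 2 (adjusted p up to 0.0232, Adcy2) and without siPwp1 replicate 1 (adjusted p up to 0.0233, Usp17lc). Olfr995, Usp17lc, Slc4a10, Zscan4d and Ebf1 were called without siPwp1 replicate 2 (adjusted p up to 0.0122, Usp17lc), and Slc4a10 without siControl replicate 1 (adjusted p = 0.0184).

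On the lower side Pwp1 had the smallest p, and the other 9 named genes did not pass (edgeR adjusted p = 0.9998 each). Nlrp4c, of a gene family active in oocytes, was at 70.6 ± 6.75 and 31.1 ± 3.71 CPM, and Abhd17c at 46.2 ± 0.555 and 21.2 ± 5.11 CPM. Mgarp, a mitochondrial protein gene, was at 61.96 ± 9.95 and 28.4 ± 8.45 CPM, and Hspb8, a small heat shock protein gene, at 18.9 ± 9.84 and 6.11 ± 0.469 CPM. The RNA helicase gene Ddx17 was at 71.03 ± 29.3 and 27.1 ± 10.9 CPM, and Ankrd13a at 57.3 ± 24.4 and 23.5 ± 5.93 CPM. Adgre5 was at 15.3 ± 4.51 and 5.11 ± 0.249 CPM, Rassf3 at 10.3 ± 3.25 and 3.47 ± 0.592 CPM, and the class I histocompatibility gene H2-Q7 at 5.58 ± 0.107 and 1.62 ± 0.507 CPM. Ddx17, Ankrd13a and Adgre5 overlap genes on the other strand, and H2-Q7 has close paralogs, so these levels are uncertain. The H2-Q7 paralog H2-Q9 went the other way, and DESeq2 called it higher (log2 fold change 6.18, adjusted p = 0.00591). Without siControl replicate 2, edgeR called Hspb8 (adjusted p = 0.0331), Ddx17 (adjusted p = 0.0273) and Ankrd13a (adjusted p = 0.0373) over all genes.

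Heat shock and unfolded protein response genes were lower in siPwp1, with a median log2 fold change of -0.28 over 26 members (camera adjusted p = 0.0248). The call was lost with an estimated correlation (adjusted p = 0.856 with an estimated correlation). Of the members, 8 were separated lower and 3 separated higher, where chance gives 16.7% each, and edgeR called 0, with 2 at unadjusted p under 0.05. Bag3, a co-chaperone gene, was at 46.9 ± 16 and 21.7 ± 2.19 CPM, and Xbp1, a transcription factor gene of the unfolded protein response, at 34.5 ± 3.07 and 20.7 ± 0.00934 CPM. The mitochondrial chaperonin gene Hspd1 was at 457.6 ± 26.4 and 321.9 ± 26.5 CPM, and Herpud1 at 4.71 ± 0.0901 and 2.20 ± 0.809 CPM. The list's call was lost without siControl replicate 1 (adjusted p = 0.242), without siPwp1 replicate 2 (adjusted p = 0.14) and with the stricter filter (adjusted p = 0.0928), and its median was -0.03 without siControl replicate 1, -0.14 without siPwp1 replicate 2 and -0.55 without siPwp1 replicate 1.

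Genes of cell junctions, polarity and cavitation were lower as well, with a median log2 fold change of -0.30 over 45 members (camera adjusted p = 0.0248). This call too was lost with an estimated correlation (adjusted p = 0.978 with an estimated correlation). Of the members, 7 were separated lower and 3 separated higher, where chance gives 16.7% each, and edgeR called 0, with 3 at unadjusted p under 0.05. Aqp3, a water channel gene, was at 94.4 ± 13.4 and 52.4 ± 0.982 CPM, and Prkci, a polarity kinase gene, at 52.3 ± 16.6 and 29.6 ± 4.99 CPM. Dsp, which encodes desmoplakin, was at 20.2 ± 14.5 and 7.01 ± 3.01 CPM, and Marveld2, a tight junction gene, at 11.4 ± 4.29 and 6.28 ± 0.101 CPM. Replicate 2 was below replicate 1 for this list in both groups, with median log2 differences of -0.72 in siControl and -0.33 in siPwp1. Without siControl replicate 1 the median turned to 0.08 (adjusted p = 0.979), and the call was lost without siPwp1 replicate 2 (adjusted p = 0.506) and with no filter (adjusted p = 0.0541). The median was -0.65 without siControl replicate 2, where edgeR called Dsp over all genes (adjusted p = 0.0331), -0.47 without siPwp1 replicate 1 and -0.18 without siPwp1 replicate 2.

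Targets of p53 were higher, with a median log2 fold change of 0.19 over 36 members (camera adjusted p = 0.0338). With an estimated correlation the call was lost (adjusted p = 0.856 with an estimated correlation). Of the members, 10 were separated higher and 1 separated lower, where chance gives 16.7% each. The death receptor gene Fas was at 0.628 ± 0.437 and 5.58 ± 0.368 CPM, the repair gene Ercc5 at 12.5 ± 3.62 and 30.1 ± 15.3 CPM, and the kinase gene Plk2 at 15.97 ± 10.6 and 43.4 ± 15.9 CPM. Mdm2, which encodes a ubiquitin ligase for p53, was at 75.8 ± 2.17 and 113.9 ± 6.25 CPM, and the cell cycle inhibitor gene Cdkn1a at 131.2 ± 44.2 and 173 ± 22.3 CPM. Adjusted over the list alone edgeR called 0 members, as over all genes, with 5 at unadjusted p under 0.05, and DESeq2 called Fas (adjusted p = 0.0115). The list's call was lost without siControl replicate 1 (adjusted p = 0.422), siPwp1 replicate 1 (adjusted p = 0.171) or siPwp1 replicate 2 (adjusted p = 0.111), and with no filter (adjusted p = 0.121). The median was 0.35 without siPwp1 replicate 1. Without siControl replicate 2 it was 0.43, and edgeR called Plk2 over all genes (adjusted p = 0.0146).

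Blood and immune genes, fixed as markers of other cell types, were higher, with a median log2 fold change of 0.87 over 5 measured members (camera adjusted p = 0.0325; adjusted p = 0.856 with an estimated correlation). Cd52 was at 0.476 ± 0.0624 and 2.18 ± 0.832 CPM, Coro1a at 1.13 ± 1.26 and 1.83 ± 0.099 CPM, and the globin gene Hba-a2 at 21.5 ± 14.4 and 39.2 ± 0.142 CPM. Hba-a1, a near copy of Hba-a2, had no count in replicate 1 of either group. The call was lost without siControl replicate 1 (adjusted p = 0.25), without siPwp1 replicate 2 (adjusted p = 0.205), with no filter (adjusted p = 0.064) and with DESeq2 (adjusted p = 0.0549), and the median was 0.55 without siControl replicate 1 and 2.06 without siControl replicate 2.

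Of the 26 lists tested, these 5 were called by camera at its preset correlation, and 0 held with an estimated correlation or by fry, directional or mixed. For the 2-cell list the unadjusted p was 0.0845 by camera with an estimated correlation, 0.0625 by directional fry and 0.00983 by mixed fry. The estimated correlation was 0.0136 for the p53 list and -0.164 for the blood and immune list, against the preset 0.01. For these 2 lists a higher correlation thus accounts for little of the loss of the call. It was 0.0367 for the heat shock list, 0.29 for the 2-cell list and 0.338 for the list of cell junctions, polarity and cavitation. In the last 2 lists correlation between members may have added to the loss, and the camera p at the preset correlation leaves it out. With so few libraries these tests could hardly call a list. The number called was 1 without siControl replicate 1, 10 without siControl replicate 2 and 1 without siPwp1 replicate 2.

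**Figure D2:**
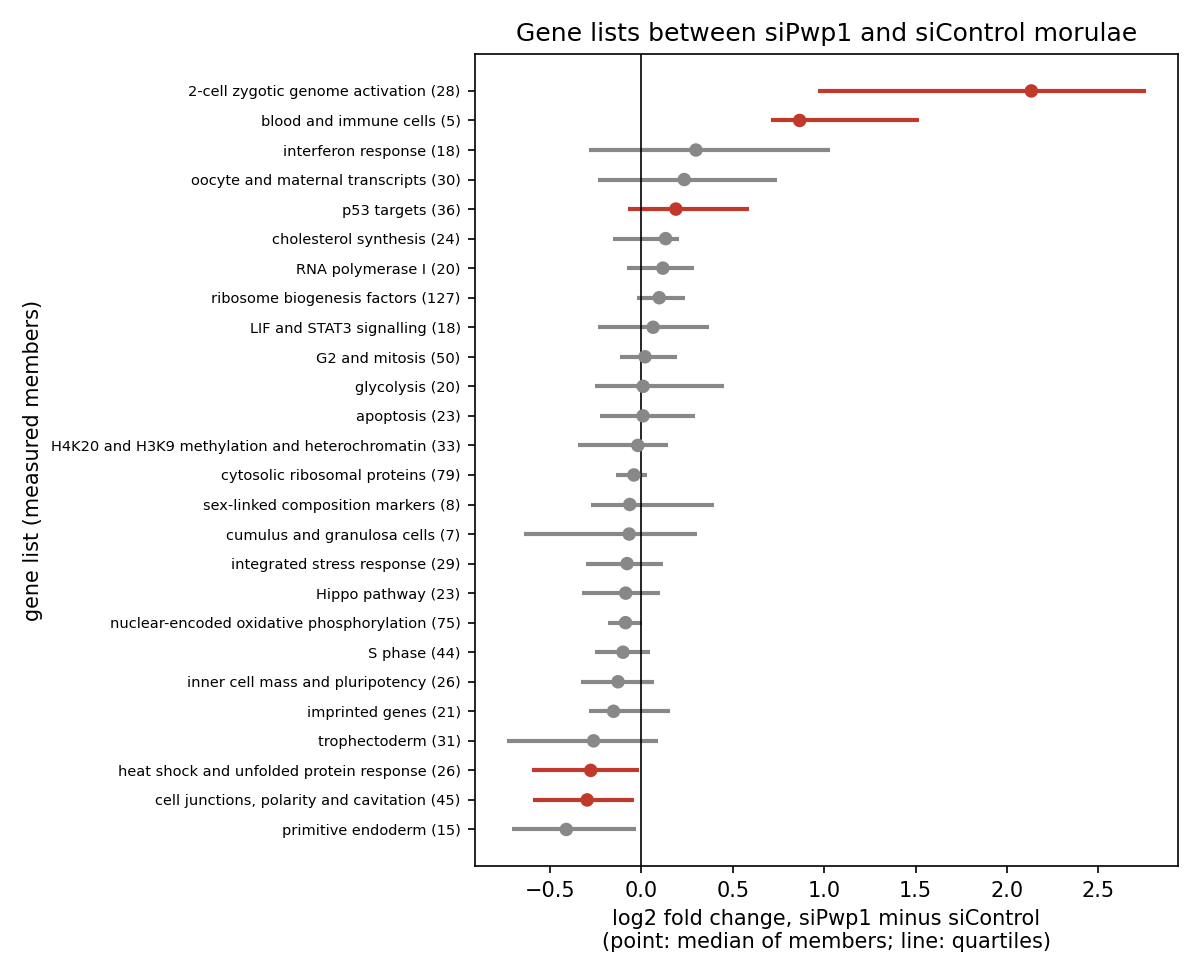
Median (point) and quartiles (line) of the log2 fold change, siPwp1 minus siControl, over the measured members of each of the 26 gene lists, with the number of members in brackets. The 5 lists called by camera at its preset correlation are red, and the 2-cell list has a median of 2.13, with the others between -0.41 and 0.87.

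The lineage lists of the forming blastocyst were not called. Trophectoderm genes had a median log2 fold change of -0.26 over 31 members (adjusted p = 0.509), inner cell mass and pluripotency genes -0.13 over 26 (adjusted p = 0.226), and primitive endoderm genes -0.41 over 15 (adjusted p = 0.509). The trophectoderm regulator Cdx2 was at 15.4 and 2.14 CPM in siControl replicates 1 and 2 and at 5.76 and 0.897 CPM in siPwp1 replicates 1 and 2. Gata3 was at 126.3, 22.7, 48.1 and 16.97 CPM in the same order, and the keratin gene Krt8 at 192.7, 15.6, 116.4 and 21.3 CPM. For these 3 genes the siControl replicates differed more than the group means did. Tead4 stood at 41.9 ± 10.3 and 34.9 ± 2.76 CPM. Among pluripotency genes, Nanog stood at 356.7 ± 92.9 and 235.5 ± 53.2 CPM, Pou5f1 at 68.4 ± 15.2 and 55.5 ± 1.39 CPM and Tfcp2l1 at 189.4 ± 75.9 and 103.1 ± 3.67 CPM. Sox2 was at 8.15 CPM in siControl replicate 1 and at 0.205, 0.732 and 0.233 CPM in the other libraries. Gata6 stood at 214.5 ± 77.4 and 178.7 ± 17.3 CPM, and Lamc1, a laminin gene, at 24.0 ± 5.47 and 11.8 ± 0.749 CPM. Other members were at higher levels in siPwp1, with the primitive endoderm regulator gene Gata4 at 4.22 ± 2.39 and 8.93 ± 1.69 CPM and the trophectoderm list member Ly6a at 575.6 ± 29.1 and 859.7 ± 129.7 CPM, both separated and neither called over all genes. Duoxa2 was at 0.804 ± 0.237 and 5.98 ± 7.65 CPM, and its log2 fold change of 2.89 turned to -0.47 without siPwp1 replicate 2, while edgeR called it without siPwp1 replicate 1 (adjusted p = 0.000664) and without a filter (adjusted p = 0.0175). Without siControl replicate 1 the log2 fold changes of Cdx2, Gata3, Krt8, Sox2 and Gata6 turned to 0.65, 0.52, 2.15, 1.24 and 0.16. Without siPwp1 replicate 2 that of Krt8 turned to 0.17, and without siControl replicate 2 that of Tead4 to 0.01. The median of the trophectoderm list turned to 0.60 without siControl replicate 1 (adjusted p = 0.33), and that of the primitive endoderm list to 0.00 (adjusted p = 0.545). That of the inner cell mass list was -0.02 without siPwp1 replicate 1 and -0.29 without siPwp1 replicate 2. Without siControl replicate 2 the trophectoderm list was called lower (adjusted p = 0.00647), as were Gata3 (adjusted p = 0.0238) and Sox2 (adjusted p = 0.012). Without siPwp1 replicate 1 edgeR called Cdx2 (adjusted p = 0.0411), Gata3 (adjusted p = 0.0273) and Krt8 (adjusted p = 0.00747) lower.

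**Figure D3:**
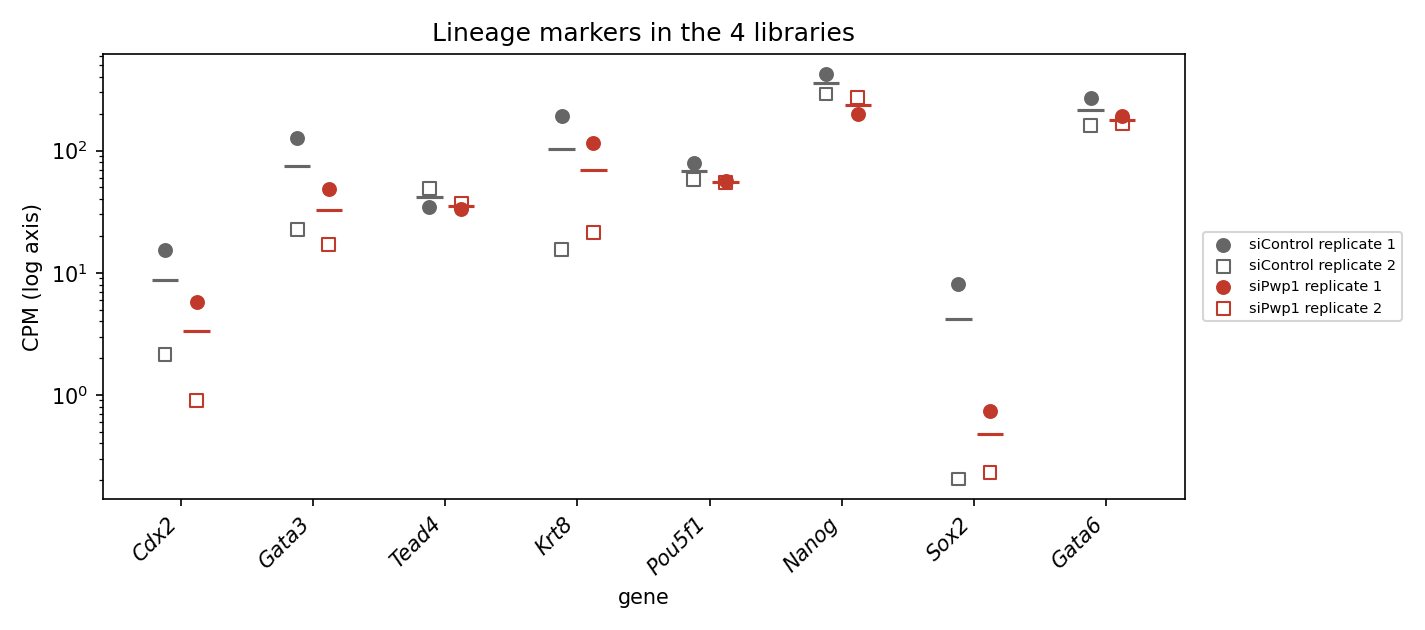
CPM on a log axis for 8 lineage markers, with 1 point per library (siControl grey, siPwp1 red; filled circles replicate 1, open squares replicate 2) and bars at group means. For Cdx2, Gata3 and Krt8 replicate 1 lies above replicate 2 within each group, as with Krt8 at 192.7 and 116.4 against 15.6 and 21.3 CPM.

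Lists tied to the known roles of Pwp1 were not called either. Ribosome biogenesis factors had a median log2 fold change of 0.10 over 127 members (adjusted p = 0.299), with 16 separated higher and 7 separated lower where chance gives 16.7% each. Urb2 was at 15.9 ± 0.796 and 10.3 ± 1.14 CPM and Wdr55 at 16.01 ± 3.65 and 23.6 ± 4.9 CPM. Genes of RNA polymerase I, which transcribes ribosomal RNA, had 0.12 over 20 (adjusted p = 0.556), with Taf1d at 210.8 ± 28.3 and 280.9 ± 10.3 CPM. Their median ran from 0.02 to 0.22 with 1 library left out. Cytosolic ribosomal protein genes had -0.04 over 79 (adjusted p = 0.556), with Rpl41 at 2151 ± 83.9 and 2703 ± 216.5 CPM. Ribosome biogenesis factors were called higher with the stricter filter (adjusted p = 0.00976) and without siControl replicate 2 (adjusted p = 0.0134), where ribosomal protein genes were called lower (adjusted p = 0.0264). Without siControl replicate 1 the medians of these lists turned to -0.03 and 0.12, and without siPwp1 replicate 2 to -0.01 and 0.05. Genes of H4K20 and H3K9 methylation and heterochromatin had a median of -0.02 over 33 (adjusted p = 0.801), which turned to 0.03 without siControl replicate 1. The H4K20 methyltransferase genes Kmt5a, Kmt5b and Kmt5c, listed in the files as Setd8, Suv420h1 and Suv420h2, were at 119.3 ± 13.5 and 111.1 ± 28.6 CPM, 34.9 ± 3.33 and 42.3 ± 4.11 CPM, and 2.30 ± 0.814 and 1.81 ± 0.21 CPM. The demethylase gene Kdm4a was at 1.18 ± 0.444 and 5.38 ± 0.47 CPM and Hells, a chromatin remodeller gene, at 140.0 ± 1.18 and 94.2 ± 2.87 CPM, and neither passed when adjusted over the list alone or over all genes. The log2 fold change of Setd8 turned to 0.01 without siControl replicate 2 and 0.14 without siPwp1 replicate 1, and that of Suv420h2 to 0.07 without siControl replicate 1.

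S phase genes had a median log2 fold change of -0.10 over 44 members (adjusted p = 0.132), with 11 separated lower and 1 separated higher where chance gives 16.7% each. Their median ran from -0.19 to -0.06 with 1 library left out. The replicative helicase gene Mcm4 was at 144.5 ± 22.6 and 85.6 ± 1.56 CPM. Mitotic genes had 0.02 over 50 (adjusted p = 0.86), with Kif2c at 26.3 ± 3.77 and 47.9 ± 4.42 CPM. Interferon response genes had 0.30 over 18 (adjusted p = 0.0995), with Ifi35 at 22.7 ± 0.309 and 46.6 ± 8.67 CPM, and were called higher without siPwp1 replicate 1 (adjusted p = 0.0455), while the median turned to -0.11 without siPwp1 replicate 2. Oocyte and maternal transcripts had 0.23 over 30 (adjusted p = 0.299) and were called higher without siControl replicate 2 (adjusted p = 0.0159) and without siPwp1 replicate 1 (adjusted p = 0.0278), while the median turned to -0.10 without siControl replicate 1 and to -0.24 without siPwp1 replicate 2. Hippo pathway genes had -0.09 over 23 (adjusted p = 0.509), with Amot, an angiomotin gene, at 47.2 ± 14.8 and 26.5 ± 2.67 CPM, and Amotl1 at 1.014 ± 0.207 and 2.73 ± 1.4 CPM, and their median was -0.17 without siPwp1 replicate 1 and -0.34 without siPwp1 replicate 2. Apoptosis genes had 0.01 over 23 (adjusted p = 0.6), with Bcl2l11 at 19.1 ± 3.86 and 35.6 ± 1.51 CPM, and integrated stress response genes -0.08 over 29 (adjusted p = 0.732), with Ddit3 at 4.66 ± 2.5 and 11.2 ± 1.03 CPM.

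Oxidative phosphorylation genes had a median log2 fold change of -0.09 over 75 members (adjusted p = 0.248) and were called lower without siControl replicate 2 (adjusted p = 0.00647) and without siPwp1 replicate 1 (adjusted p = 0.0278), while the median turned to 0.15 without siControl replicate 1 and to 0.07 without siPwp1 replicate 2. Cholesterol synthesis genes had 0.13 over 24 (adjusted p = 0.86), and glycolysis genes 0.01 over 20 (adjusted p = 0.956), with Slc16a1, a lactate transporter gene, at 68.3 ± 21.1 and 35.5 ± 3.52 CPM. The glycolysis median ran from -0.55 to 0.43 with 1 library left out. Cumulus and granulosa markers had -0.07 over 7 (adjusted p = 0.738). For imprinted genes (21 members, adjusted p = 0.86) the median was -0.15, the mean 0.01 and the test's direction down. For sex-linked genes (8 members, adjusted p = 0.956) the median was -0.06, the mean 0.09 and the direction up. For LIF and STAT3 genes (18 members, adjusted p = 0.956) the median was 0.06, the mean 0.11 and the direction down. Of the 26 lists, 17 had a median that changed sign when some single library was left out.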

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

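The test by limma on log2(TPM + 1) was chosen after seeing the data, and the other settings were fixed before. Pseudocount and quantile alternatives applied to files without counts and were not run. DESeq2 size factors gave 861 and 317 separated 2-fold genes and changed no call or direction, and a threshold of 0.1 gave 0 genes higher and 0 lower. With no filter, Pwp1 had a log2 fold change of -2.98 and passed, edgeR called 99 genes higher and 7 lower, 1314 and 703 were separated and at least 2-fold changed, and 2 lists were called. The prior degrees of freedom of that fit were infinite, against 4.84, so its p-values are far smaller (Pwp1 adjusted p = 5.04e-16) and its calls are not comparable. The stricter filter left 134 and 41 separated 2-fold genes, of fewer tested. DESeq2 put Pwp1 at -2.96, past the threshold, with 42 genes higher and 2 lower, and limma gave 166 and 29 separated 2-fold genes. The cause was not tested for DESeq2 and limma.

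The replicate numbers share no day or culture in the labels. Across genes, the differences between replicate numbers correlated at 0.317 in the 2 groups. With the replicate block, Pwp1 had a log2 fold change of -2.92 and passed, and 71 genes were called higher and 9 lower. Of these 80, 37 were among the 44 called by DESeq2 and 10 were members of the 2-cell list. Each gene named on the higher side was called, with adjusted p values from 0.0014 (Olfr995) to 0.0256 (Ercc4). This fit had prior degrees of freedom of 10.3, against 4.84 without the block. Its calls thus do not compare like with like. On the lower side Nlrp4c (adjusted p = 0.0256), Mgarp (0.0409), Ddx17 (0.0127) and Ankrd13a (0.0367) were called with the block, beside Pwp1. The other genes named there were not called. The p53 list was not called with the block (adjusted p = 0.0551), while its member Fas was called higher (adjusted p = 0.0424).

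Leaving out each library in turn, Pwp1 ranged from -3.30 to -2.54, genes called higher from 5 to 130 and lower from 1 to 18, separated 2-fold genes from 1203 to 1800 higher and from 525 to 1359 lower, and called lists from 1 to 10. A group of 1 library is easier to separate, and the prior degrees of freedom were 9.8 to infinite in these fits. At the preset correlation the 2-cell list was called without each library (adjusted p from 1.84e-18 to 8.11e-09, medians 1.73 to 3.67) and in the other settings (down to 5.37e-36 with DESeq2), but not with an estimated correlation (adjusted p = 0.856) or by fry (adjusted p = 0.864). The direction turned within these ranges of log2 fold changes: Cdx2 -3.28 to 0.6454, Gata3 -2.13 to 0.523, Krt8 -2.29 to 2.15 (0.1672 without siPwp1 replicate 2), Sox2 -4.14 to 1.24, Gata6 -0.59 to 0.1616, Tead4 -0.49 to 0.01229, Setd8 -0.39 to 0.1384, Suv420h2 -0.67 to 0.06549, Uhrf1 -2.54 to 0.4622, Coro1a -0.145 to 2.90, Tsix -1.08 to 0.1819, Duoxa2 -0.4749 to 3.83, Insig1 -1.55 to 0.09721, Phlda2 -0.321 to 2.08, Kdm5d -0.07778 to 2.02, Hba-a1 -6.80 to 8.14, and the median of the list of cell junctions, polarity and cavitation -0.65 to 0.07602. The cause was not tested.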

Other observations

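The tests of shared reads between copies, of maternal transcripts, of Y-linked genes and of a shared culture round were chosen only after the result was seen. Bootstrap intervals given below resample genes, not libraries. They leave out the spread between libraries and treat genes as independent. Among maternal transcripts, which the oocyte stores and the embryo clears, 7 were separated higher and 4 separated lower in siPwp1, where chance gives 16.7% each. Rfpl4 stood at 0.844 ± 0.132 and 3.54 ± 0.311 CPM (SD, n = 2), and Btg4, a gene of maternal RNA decay, at 1.28 ± 0.536 and 5.74 ± 3.2 CPM. In the glycolysis list Pdk1, a kinase gene that restrains pyruvate oxidation, stood at 0.2005 ± 0.0382 and 1.76 ± 0.612 CPM. None of these 3 genes passed edgeR over all genes.

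The 2-cell list was called higher in siPwp1 by camera at its preset correlation, but not with an estimated correlation (adjusted p = 0.856) or by fry (adjusted p = 0.864), and edgeR called 0 of its members over all genes, with 13 at unadjusted p under 0.05 and 6 called by DESeq2. Reads moving between copies would leave family sums level. Of the 5 family sums, 4 (Zscan4, Tcstv, Usp17l and Tdpoz, not Obox) were separated and 3.76-fold to 10.3-fold higher. This argues against reads moving among the copies summed in those 4 families, while for Obox3 it stays open. The list members of those 4 families were each higher already, so the sums add little. Reads from copies outside the sums were not tested. A shift along the difference between replicate numbers would need a slope of 2.98. The 500 genes outside the list that differ most between the numbers had a slope of 0.145 (95% bootstrap interval 0.0995 to 0.194) and a correlation of 0.521. These genes were picked by the smallest p of a test in which a group difference counts as spread, which favours a low slope. The same 4 libraries also enter both contrasts, so this test cannot decide and the shift stays open. Some embryos halted near the 2-cell stage would also carry maternal transcripts, whose median of 0.235 (interval -0.0848 to 0.434) leaves this open, and it cannot be told apart from a change of these genes within morulae, which was not tested.

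Trophectoderm genes differed between the siControl replicates, with a median log2 difference, replicate 2 minus replicate 1, of -1.32 (95% bootstrap interval -1.92 to -0.212), against -0.27 in siPwp1 (interval -0.768 to 0.312) and -0.24 over both groups together, where siPwp1 against siControl gave -0.26 and the remaining split of the 4 libraries 0.48. Replicate 2 against replicate 1 gave 5 genes called by edgeR and 2263 at unadjusted p under 0.05 among all genes, against 0 and 362 for the real groups (44 called by DESeq2), which points to a structure of the samples. Thinning all libraries to the smallest total left -1.27 in siControl (interval -1.99 to -0.208). Thinning keeps CPM level on average, so this result could not count for or against library size. The share of male embryos stays open, since Y-linked genes differed by a median of -0.97 in siControl and 0.7465 in siPwp1 while the trophectoderm interval in siPwp1 includes 0. A shared culture round or stage at collection stays open too, since the correlation of 0.317 between the replicate differences rests on 2 pairs.

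Among separated genes at least 2-fold apart, 857 were higher and 323 lower, with 342 of the higher and 138 of the lower genes under 1 CPM, and 360 and 128 from 1 to 5 CPM. After thinning to the smallest total the ratio of higher to lower had a median of 2.585 over 20 draws (2.50 to 2.71). Before thinning it was 2.69, from the 846 higher and 315 lower genes that log2 CPM gives. The excess of higher genes thus remained at equal totals. Thinning keeps CPM level on average, however, so this result could hardly count for or against library size. As a biological hypothesis, wider expression of silent receptor families was tested on 1462 olfactory and vomeronasal receptor genes. At equal total counts 175 and 85 of them were detected in siControl and 147 and 157 in siPwp1, a 1.167-fold difference of the means with overlapping ranges; both outcomes set beforehand as against the hypothesis (overlap, or under 1.5-fold) were met, but single libraries give 0.838-fold to 1.84-fold, so neither could exclude it at this spread and it stays open. Their summed counts, looked at afterwards, were separated, at 621 and 603.2 in siControl against 1695 and 2519 in siPwp1, or 611 and 596.2 against 1400 and 2296 without Olfr995.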
